A study of Arabidopsis thaliana with 6 samples.

How the data were processed

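Poly(A) RNA of 6 root samples, 3 of WT Col-0 and 3 of the xal1-2 mutant, was sequenced as stranded paired-end libraries, per the labels. Seedlings were grown on vertical plates of 0.2X MS salts with 1% sucrose at 22 °C, with 16 h of light and 8 h of dark. Per the submitters' processing notes, the tools were FastQC 0.11.9, Trimmomatic 0.39, Subread 2.0.1 and DESeq2, with the TAIR10 build; no settings are given in the sources used here. The aligner's treatment of reads that match several genes and the strand setting of the counting are not given in the sources used here, so genes with near-identical copies and overlapping genes are uncertain.

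The authors deposited a table of 32833 genes. Its library columns hold a signal that the authors had made, before deposit, by dividing the read counts of each gene by a size factor per library, as the deposited values show. Within a tolerance of 0.001 of a read, 100.0% of the values above 0 in each library came out as whole reads after multiplication by the size factor, and these size factors equal the median of ratios recomputed from the recovered reads. Recovered totals ran from 6978879 to 9247089 reads per library, and from 21969 to 22409 genes had reads in a library. The deposited mean over the libraries is in the same unit. The table also holds the authors' deposited log2 fold change, its standard error, a score (the test statistic) and p-values with adjusted p-values per gene, named in the text as the authors' deposited table wherever used. For XAL1 alone among 24441 genes, the deposited log2 fold change (-1.57) differs from the deposited statistic multiplied by its standard error (-1.47) and from the log2 ratio of the group means (-1.47), so that deposited value was not used.

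The planned test, edgeR on raw counts, assumed a table of raw counts. Because the file holds scaled counts, the planned fallback was the main test: limma 3.58.1 in R 4.3.3, with an intensity trend in the moderated variance (limma-trend), on log2(scaled count + 1), for the 24441 genes above 0 in at least 1 library, genotype as the only term, all 6 libraries in the fit, Benjamini-Hochberg adjustment, and a gene called at adjusted p under 0.05. All adjusted p-values of single genes come from this test unless another tool is named. For genes at low level, fold changes on this scale can be smaller than the ratio of the means, or larger where a group's values are uneven, as for DOGT1 (log2 fold change 5.71, against 3.78 in edgeR). The 8392 genes at 0 in every library were not tested. Count tests on the recovered reads (edgeR 4.0.16 quasi-likelihood test with TMM factors and filterByExpr, DESeq2 1.42.0, limma-voom) were alternatives. edgeR called 1111 genes, 865 of them also called by limma-trend, and DESeq2 called 1054, 800 of them shared. Other alternatives, whose effects are given in the closing section, were library totals, TMM and upper-quartile factors, pseudocounts of 0.1 and 5, 2 filters on low values, other thresholds, the replicate number as a block, a per-library loess correction for GC content and exon length, and leaving out each library in turn. The groups, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The edgeR test of the recovered reads, TMM factors within limma and the GC and length correction were added after.

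No 2 libraries agreed within sampling noise: the chi-square statistic per degree of freedom between libraries of a genotype ran from 3.94 to 9.70, so all 6 counted as separate samples. Replicates are biological per the labels.

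Gene lists (24, written from gene identifiers, and 3 from product names in the reference) were tested with camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over 27 lists, with camera at an estimated correlation and fry beside it. With the preset correlation 10 lists were called. With an estimated correlation 0 were (1 at an unadjusted p under 0.05), the smallest adjusted p being 0.349, and the directional fry test called 1, the xylem list. The mixed fry test, which asks for members moving in either direction, also called lists that camera did not call. Among them were G1/S (adjusted p = 0.000339), lateral root (0.000339), glutathione S-transferases (0.000339), root MADS-box (0.00148), antioxidant (0.00852) and auxin (0.0212). It did not call G2/M (0.266), cell cycle inhibitors (0.471), NADPH oxidases (0.311) or rapid stress (0.726), among others. Of the list members, 1 was dropped because the reference gives its identifier another name. Lists of genes, 73 peroxidases among them, were checked against the reference annotation (TAIR10.1), in which 32548 identifiers of the table matched and 285, those of organelle genes, did not. Coordinates are those of TAIR10.1 and were not converted.

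The text names XAL1, its measured neighbours and UPB1. It also names the 5 largest rises and the 5 largest falls among called genes with a mean at or above the median over all genes (32.6 scaled counts) and no overlap between genotypes. From the lists it names the called members of smallest adjusted p, up to 6 peroxidases, up to 2 each of the NADPH oxidase, antioxidant, 3 cell cycle, stem cell niche and MADS-box lists, and up to 1 of each other list. Further genes named as examples of a count were chosen after their values were seen. The result of 1 Casparian strip gene is not reported singly.

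A fold against a group with 0 reads is a lower bound against a floor of 3 reads over the group's libraries together, and such bounds cover counting error only. The tests were checked on simulated counts for the xal1-2 against WT comparison, drawn for 24441 genes with the real means, library sizes and dispersions and 200 changed genes of known fold. limma-trend recovered 31.3% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 100% of those changed 4-fold, with 12 false calls among 150, and edgeR recovered 37.3%, 80.6% and 100%, with 14 false among 159. In this simulation a change of 1.5-fold was often missed at this depth, spread between replicates and number of replicates. With 150 called genes there, against 961 in the data, the adjustment asked for smaller unadjusted p, so recovery in the data may be higher. The changed genes came from a middle range of mean reads, so genes of lower level are not covered.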

Results

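RNA was sequenced from 6 samples of Arabidopsis thaliana root, 3 from the wild-type accession Col-0 (WT) and 3 from xal1-2, a loss-of-function mutant of XAANTAL1 (XAL1, also called AGL12), which encodes a MADS-box transcription factor. Each biological replicate pooled roots of about 60 seedlings at 8 days after sowing, with the hypocotyl and cotyledons removed. The series states that roots of the mutant are short and their cells divide slowly, and asks which genes change in the mutant root. Reads assigned to genes numbered 7929009, 7740207 and 8962691 in WT replicates 1, 2 and 3, and 6978879, 9247089 and 9191144 in xal1-2 replicates 1, 2 and 3. Values below are read counts scaled for depth, given as mean ± SD over 3 replicates, and log2 fold changes are xal1-2 over WT, on the log2(scaled count + 1) scale, with their standard error (SE).

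XAL1 itself was checked first. Its scaled counts were 263.8, 250.1 and 268.7 in the WT libraries and 76.5, 102.0 and 103.2 in the xal1-2 libraries, so every mutant library lay below every WT library. The mean fell from 261 ± 9.62 to 93.9 ± 15.1 (SD, n = 3 each), a log2 fold change of -1.48 (SE 0.14; limma adjusted p = 0.00034), and transcript from the locus was still detected at 0.36 of the WT mean. XAL1 (AT1G71692) lies on the minus strand of chromosome 1 at 26952545 to 26955127 in the TAIR10.1 annotation, with 7 exons. The counts cover the whole gene and do not show which exons the remaining reads came from.

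Of the 3 annotated genes on either side of XAL1, 1 was called. AT1G71691, a GDSL-type lipase gene on the same strand that begins 997 bp past the 3' end of XAL1 (chromosome 1, 26948743 to 26951547), had 0 reads in all 3 WT libraries and 11, 11 and 15 reads in the 3 mutant libraries. Against a floor of 3 reads over the WT group it was at least 12-fold higher in xal1-2 (limma adjusted p = 0.000384). It overlaps AT1G71690 on the opposite strand, where scaled counts were 2.37 ± 1.13 in WT and 7.34 ± 5.25 in the mutant (adjusted p = 0.207), and how strand was used in counting is not given in the sources used here, so reads of this pair are uncertain. AT1G71680 had no reads in any library. On the other side, the peroxidase gene PER12 (AT1G71695) had a log2 fold change of -0.28 (SE 0.15, adjusted p = 0.352), SOL1 -0.23 (SE 0.14, adjusted p = 0.397) and CK1 -0.16 (SE 0.15, adjusted p = 0.618), none of them called. DESeq2 gave AT1G71691 no adjusted p.

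**Figure D1:**
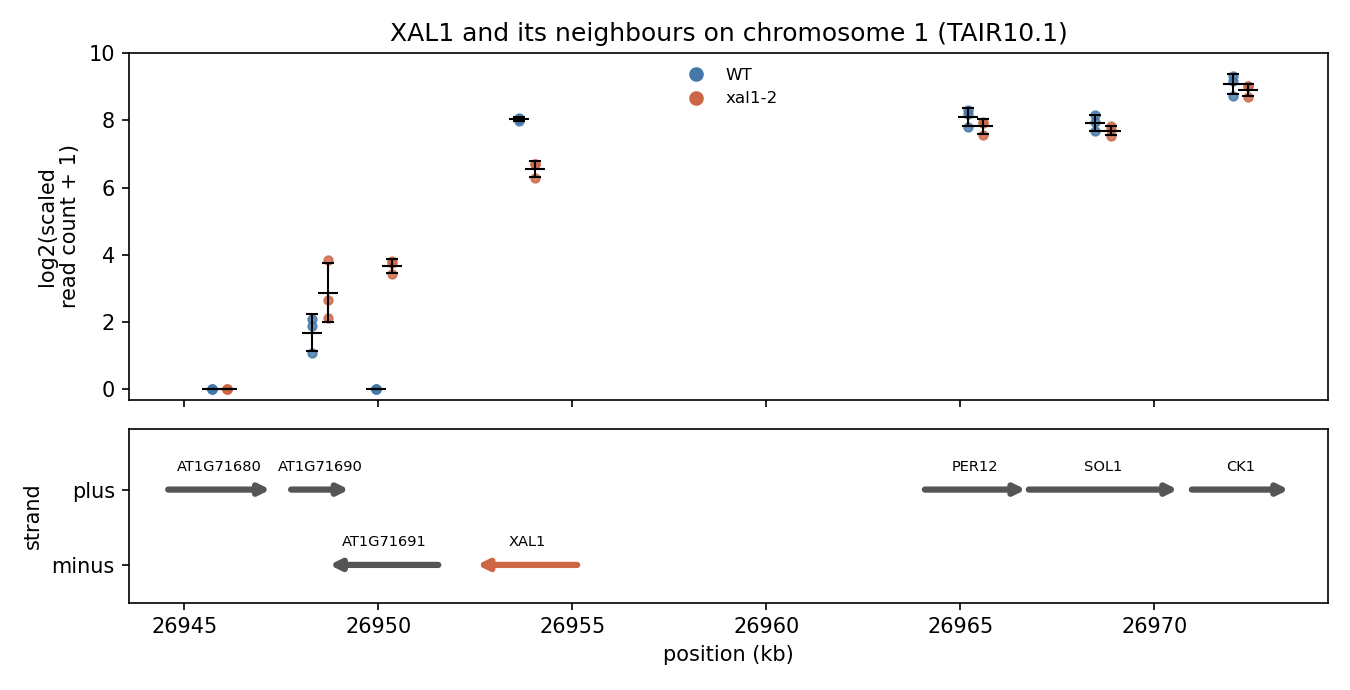
Scaled read counts, as log2(scaled read count + 1), of XAL1 and its 3 neighbours on either side in 3 WT and 3 xal1-2 libraries (points; black bars, mean ± SD on that scale), above a map of the genes by position in kb on chromosome 1, with arrows in the direction of transcription. XAL1 is lower in all 3 mutant libraries, and AT1G71691 is at 0 in WT and has 11 to 15 reads in the mutant libraries.

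Across the transcriptome, 961 of 24441 genes tested were called (limma-trend, adjusted p under 0.05), 405 higher and 556 lower in xal1-2. The study's threshold, read as a fold change above 1.5 with adjusted p under 0.05, took 703 genes, 284 higher and 419 lower. The authors' deposited table lists 1040 genes at adjusted p under 0.05, of which 799 were among the 961, and 709 past both limits. The split between directions depended on scaling: with library totals in place of size factors 989 genes were called, 582 higher and 407 lower. None of the 961 changed sign when 1 library was left out. In 959 of them the genotypes did not overlap, so their sign could not change in this way. Leaving out a library lowers power whichever library it is. The count itself varied with the library left out. It was 81 without xal1-2 replicate 1, 193 without WT replicate 2, 326 without xal1-2 replicate 2, 430 without WT replicate 1, 535 without xal1-2 replicate 3 and 871 without WT replicate 3, the library that stood apart from the other WT libraries on the second principal component (-28.8 against 11.3 and 8.3). Genes past the study threshold then numbered 81, 193, 320, 413, 498 and 694, in the same order of libraries.

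The largest rises belonged to genes close to silent in WT roots. AT5G09570, which encodes a Cox19-like CHCH protein, a class of small mitochondrial cysteine-rich proteins, rose from 8.83 ± 2.01 to 679 ± 123 (log2 fold change 6.12, SE 0.21, adjusted p = 7.97e-08). NDB4 and NDB3, alternative NAD(P)H dehydrogenases of the mitochondrial inner membrane, rose from 2.32 ± 1.29 to 211 ± 65.9 (6.03, SE 0.34, adjusted p = 5.29e-06) and from 1.34 ± 0.42 to 126 ± 9.97 (5.77, SE 0.29, adjusted p = 3.15e-06). AT5G52940, a DUF295 gene of unknown function, had 0 reads in WT and 276 in the mutant libraries together, at least 89.2-fold higher against a floor of 3 reads over the WT group. The glucosyltransferase gene DOGT1 rose from 11.3 ± 19.5 to 171 ± 20.9, but its WT reads all came from WT replicate 3. Its call was absent in edgeR (adjusted p = 0.0891), and in DESeq2 too. It has close relatives next to it on chromosome 2, so reads shared among them leave its level uncertain.

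The largest falls among genes above the median level were those of MRD1, from 278 ± 13.9 to 19.6 ± 8.5 (log2 fold change -3.86, SE 0.28, adjusted p = 3.02e-05), and of ATC, a member of the TERMINAL FLOWER 1 family, from 183 ± 40 to 12.6 ± 5.29 (-3.80, SE 0.29, adjusted p = 4.12e-05). The sugar transporter gene SWEET11 fell from 136 ± 6.55 to 16.6 ± 13.1 (-3.51, SE 0.66, adjusted p = 0.0174). AT1G65020 fell from 266 ± 16.0 to 30.8 ± 6.01 (-3.09, SE 0.18, adjusted p = 5.29e-06), and its end overlaps AT1G65010 on the opposite strand, which moved the other way. AT1G52820, a 2-oxoglutarate-dependent oxygenase gene, fell by 2.64 on the log2 scale (SE 0.48, adjusted p = 0.0157), a call that edgeR did not make (adjusted p = 0.0699). SWEET11, AT1G52820 and DOGT1 were no longer called without WT replicate 2 or xal1-2 replicate 1, nor SWEET11 without WT replicate 3, AT1G52820 without xal1-2 replicate 3 and DOGT1 without xal1-2 replicate 2 or 3 (adjusted p up to 0.109, 0.151 and 0.148).

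Class III peroxidases, the secreted enzymes that consume or produce hydrogen peroxide in the cell wall, moved in both directions. Of 68 members tested, 2 rose and 3 fell, and 63 were not called. Adjusted over the list alone, 4 rose and 8 fell. PER28 (AT3G03670) rose from 4.87 ± 1.55 to 34.3 ± 11.1 (log2 fold change 2.57, SE 0.35, adjusted p = 0.00377) and PER61 (AT5G24070) from 62.2 ± 20.3 to 122 ± 12.8 (1.01, SE 0.22, adjusted p = 0.0321). PER8 fell from 273 ± 50 to 151 ± 30.8 (-0.86, SE 0.18, adjusted p = 0.0251), PER11 from 426 ± 64.9 to 296 ± 10.4 (-0.51, SE 0.12, adjusted p = 0.0437) and PER20 from 469 ± 14.5 to 342 ± 37.4 (-0.46, SE 0.11, adjusted p = 0.0408). The list as a whole was lower (median log2 fold change -0.21, camera adjusted p = 0.00358), with adjusted p = 0.492 with an estimated correlation. UPB1, which encodes a regulator of root peroxidase genes, was at 83.4 ± 20 in WT and 70.6 ± 11.1 in the mutant (-0.22, SE 0.21, adjusted p = 0.629). DESeq2 called more of the list, with 3 higher and 9 lower. PER11 and PER20 were not called with library totals, nor PER11 with a pseudocount of 0.1. Without xal1-2 replicate 1 limma called none of the 68 (PER28 adjusted p = 0.0705, list adjusted p = 0.0655), and without WT replicates 1, 2 or 3 or xal1-2 replicates 2 or 3 it called 3, 2, 6, 2 and 3 of them. PER8 was called without 3 of the 6 libraries and PER61, PER20 and PER11 without 1 of them (adjusted p up to 0.141, 0.172, 0.152 and 0.187).

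Other genes of reactive oxygen metabolism showed few calls. Among 8 NADPH oxidase genes tested, whose products make superoxide outside the cell, RBOHD alone was called, falling from 816 ± 154 to 550 ± 17.1 (log2 fold change -0.55, SE 0.13, adjusted p = 0.0406). Adjusted over the list alone it was also the single call. Among 38 antioxidant enzyme genes, APX5, an ascorbate peroxidase gene, was the single call, over all genes and adjusted over the list alone, falling from 141 ± 12.8 to 68.6 ± 13.0 (-1.04, SE 0.18, adjusted p = 0.0105). Neither list was called by camera (adjusted p = 0.427 and 0.522). DESeq2 called 3 antioxidant genes, all lower. RBOHD was not called with library totals, a pseudocount of 0.1 or the GC and length correction, or without WT replicate 2, WT replicate 3 or any 1 xal1-2 replicate (adjusted p up to 0.195), and APX5 was not called without xal1-2 replicate 1 (adjusted p = 0.0719).

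Cell cycle genes were mostly not called. In the list of 32 G1/S and DNA replication genes, the D-type cyclins CYCD3;2 and CYCD2;1 were the 2 calls, also adjusted over the list alone, and both rose. CYCD3;2 went from 175 ± 10.3 to 290.2 ± 2.42 (log2 fold change 0.73, SE 0.11, adjusted p = 0.00507) and CYCD2;1 from 312 ± 20 to 479 ± 21.4 (0.62, SE 0.10, adjusted p = 0.00809). None of the 33 G2/M and cytokinesis genes and none of the 18 cell cycle inhibitor and endocycle genes was called by limma, edgeR, DESeq2 or limma-voom, or by limma adjusted over the list alone, and 2 and 0 of them had an unadjusted limma p under 0.05. The medians of these 3 lists were -0.04, -0.05 and -0.09, and camera called none of them (adjusted p = 0.902, 0.533 and 0.475). The G1/S list had a median below 0 and a camera direction above it, and with library totals both its median and that of the G2/M list turned above 0 (0.017 and 0.015). The G1/S median was also above 0 without WT replicate 3 (0.028) or xal1-2 replicate 3 (0.069). Without xal1-2 replicate 1 both cyclins lost their call (adjusted p = 0.0583 and 0.0585).

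Among 26 regulators of the stem cell niche and columella, PLT3, one of the PLETHORA factors that maintain the root meristem, rose from 115 ± 12.3 to 181 ± 34.1 (log2 fold change 0.64, SE 0.16, adjusted p = 0.0499). It was the single member called; adjusted over the list alone limma called none, with 5 at an unadjusted p under 0.05, and edgeR called 2. The list was not called by camera (median 0.08, adjusted p = 0.0523) but was without WT replicate 2 or xal1-2 replicate 3 (0.0317 and 0.0123) and with library totals (0.0443). The related PLT1 was at 46.4 and 73.1 in WT and mutant (adjusted p = 0.111) and WOX5 at 7.12 and 10.9 (adjusted p = 0.432). Of 11 other root MADS-box genes tested, AGL42 fell from 181 ± 7.63 to 88.3 ± 3.35 (-1.03, SE 0.13, adjusted p = 0.00202), the single call over all genes and over the list alone, in a list that camera did not call (adjusted p = 0.539, median 0.03, or -0.04 without xal1-2 replicate 1, and camera direction below 0). PLT3 was not called by limma-voom, with pseudocounts of 0.1 or 5 or after the GC and length correction, and lost its call without any library but xal1-2 replicate 3 (adjusted p up to 0.212), while AGL42 was called without any 1 library.

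**Figure D2:**
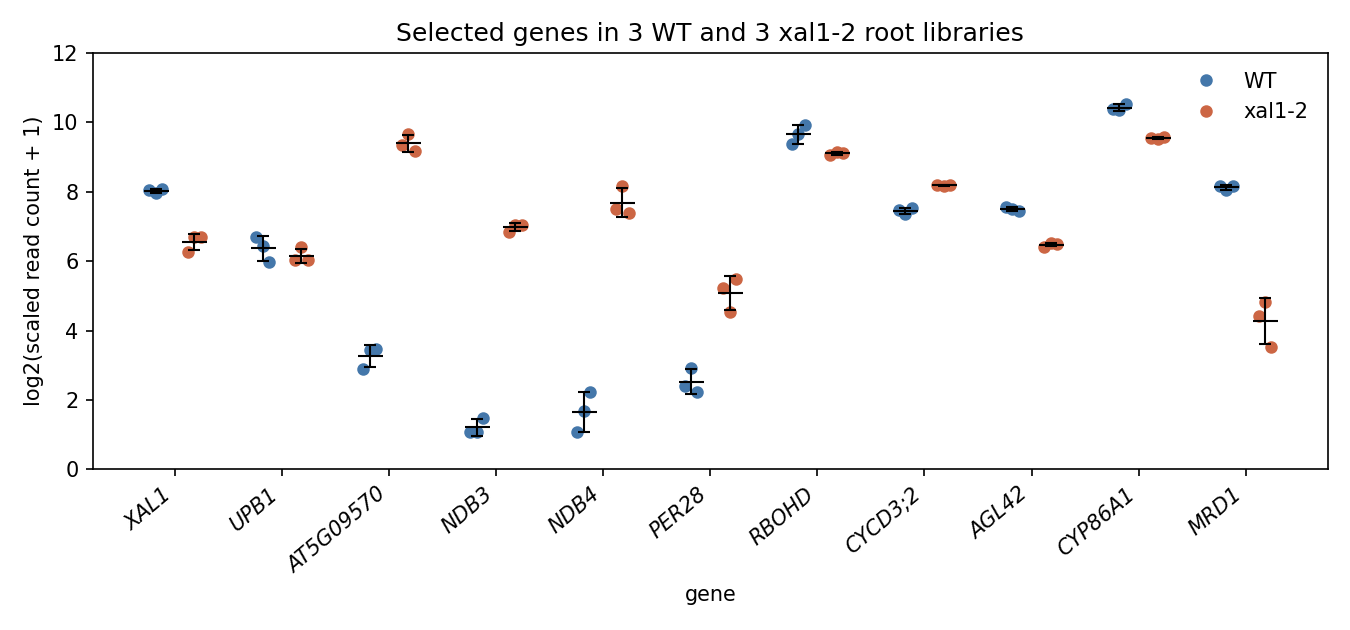
log2(scaled read count + 1) of 11 genes in 3 WT and 3 xal1-2 libraries; points are libraries and black bars the mean ± SD on that scale. XAL1 fell from 261 to 93.9 scaled counts and AT5G09570 rose from 8.83 to 679, while the libraries of UPB1 overlap between genotypes.

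Among 54 tested genes of differentiated inner root tissues, in 4 lists, 22 fell and 32 were not called, and camera called each list lower (adjusted p = 0.349 with an estimated correlation for each). Suberin is the lipid barrier polymer of the endodermis, and 6 of its 14 synthesis and export genes fell (11 adjusted over the list alone). CYP86A1 went from 1379 ± 95.2 to 748 ± 15.9 (log2 fold change -0.88, SE 0.10, adjusted p = 0.000807), and GPAT5, ABCG2, ABCG6, ABCG20 and KCS2 fell by 0.62 to 0.98 on the log2 scale. Of 9 Casparian strip genes, which build the diffusion barrier in endodermal walls, 5 fell (7 over the list alone), CASP5 most, from 195 ± 20 to 87.4 ± 22.3 (-1.17, SE 0.18, adjusted p = 0.00648), with ESB1 and SGN3 among the others. Of 19 xylem and secondary wall genes, 7 fell (13 over the list alone), among them the cellulose synthases CESA7 and CESA8 and the laccase gene LAC11, from 619 ± 58.5 to 376 ± 18.0 (-0.71, SE 0.10, adjusted p = 0.00469). Of 12 phloem genes, 4 fell (7 over the list alone), namely SEOR1, SEOR2, OPS and the sucrose carrier gene SUC2. SEOR2, a sieve element protein gene, went from 516 ± 103 to 232 ± 27.8 (-1.14, SE 0.15, adjusted p = 0.00249).

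The medians of these lists were -0.53 for suberin, -0.50 for the Casparian strip, -0.46 for xylem and -0.68 for phloem, with camera adjusted p = 1.62e-10, 3.74e-07, 1.13e-10 and 5.99e-05. The rotation test fry, which asks whether members move one way on balance, called the xylem list (adjusted p = 0.044) and not suberin (0.0533), the Casparian strip (0.0654) or phloem (0.102). Without xal1-2 replicate 1, CASP5, LAC11 and SEOR2 missed the threshold (adjusted p = 0.0852, 0.0585 and 0.0552), while CYP86A1 was called without any 1 library. The numbers of genes that fell were 3 for suberin and 0 for the other lists without xal1-2 replicate 1, with all 4 lists still called by camera. Without WT replicates 1, 2 or 3 or xal1-2 replicates 2 or 3 they were 6, 4, 5, 5 and 5 for suberin, 1, 1, 7, 2 and 1 for the Casparian strip, 2, 2, 3, 1 and 3 for xylem, and 3, 1, 1, 1 and 1 for phloem. With library totals 4 xylem and 2 phloem genes fell, after the GC and length correction 3 Casparian strip and 2 phloem genes, and with a pseudocount of 0.1, 2 phloem genes.

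Outer and other tissue markers gave no such counts, which by itself shows no difference from the inner tissues. In the root hair list 18 of 21 members were below 0, with a mean log2 fold change of -0.25 (SE 0.27). That spread does not exclude a fall as large as in the inner tissue lists. None of 21 root hair genes, 5 non-hair epidermis genes and 26 photosynthesis genes (markers of green tissue) was called by limma, over all genes or over the list alone, with 2, 1 and 2 at an unadjusted p under 0.05. DESeq2 called 1 root hair gene, and edgeR and limma-voom called none in the 3 lists. Camera called the root hair list lower (median -0.27, adjusted p = 0.00905), with adjusted p = 0.726 with an estimated correlation, and that call was absent without xal1-2 replicate 1, WT replicate 1 or WT replicate 2 (adjusted p = 0.359, 0.102 and 0.27). The non-hair and photosynthesis lists were not called (adjusted p = 0.442 and 0.751), except the latter without xal1-2 replicate 3 (adjusted p = 0.000613), where 2 of its genes fell; leaving out xal1-2 replicate 2, 1 gene rose. Of 11 lateral root genes LRP1 rose from 91.5 ± 3.06 to 153 ± 16.6 (log2 fold change 0.73, SE 0.14, adjusted p = 0.0185). Over the list alone 1 rose and 2 fell, and camera did not call the list (adjusted p = 0.554). LRP1 was not called without WT replicate 2, xal1-2 replicate 1 or xal1-2 replicate 2 (adjusted p up to 0.11).

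**Figure D3:**
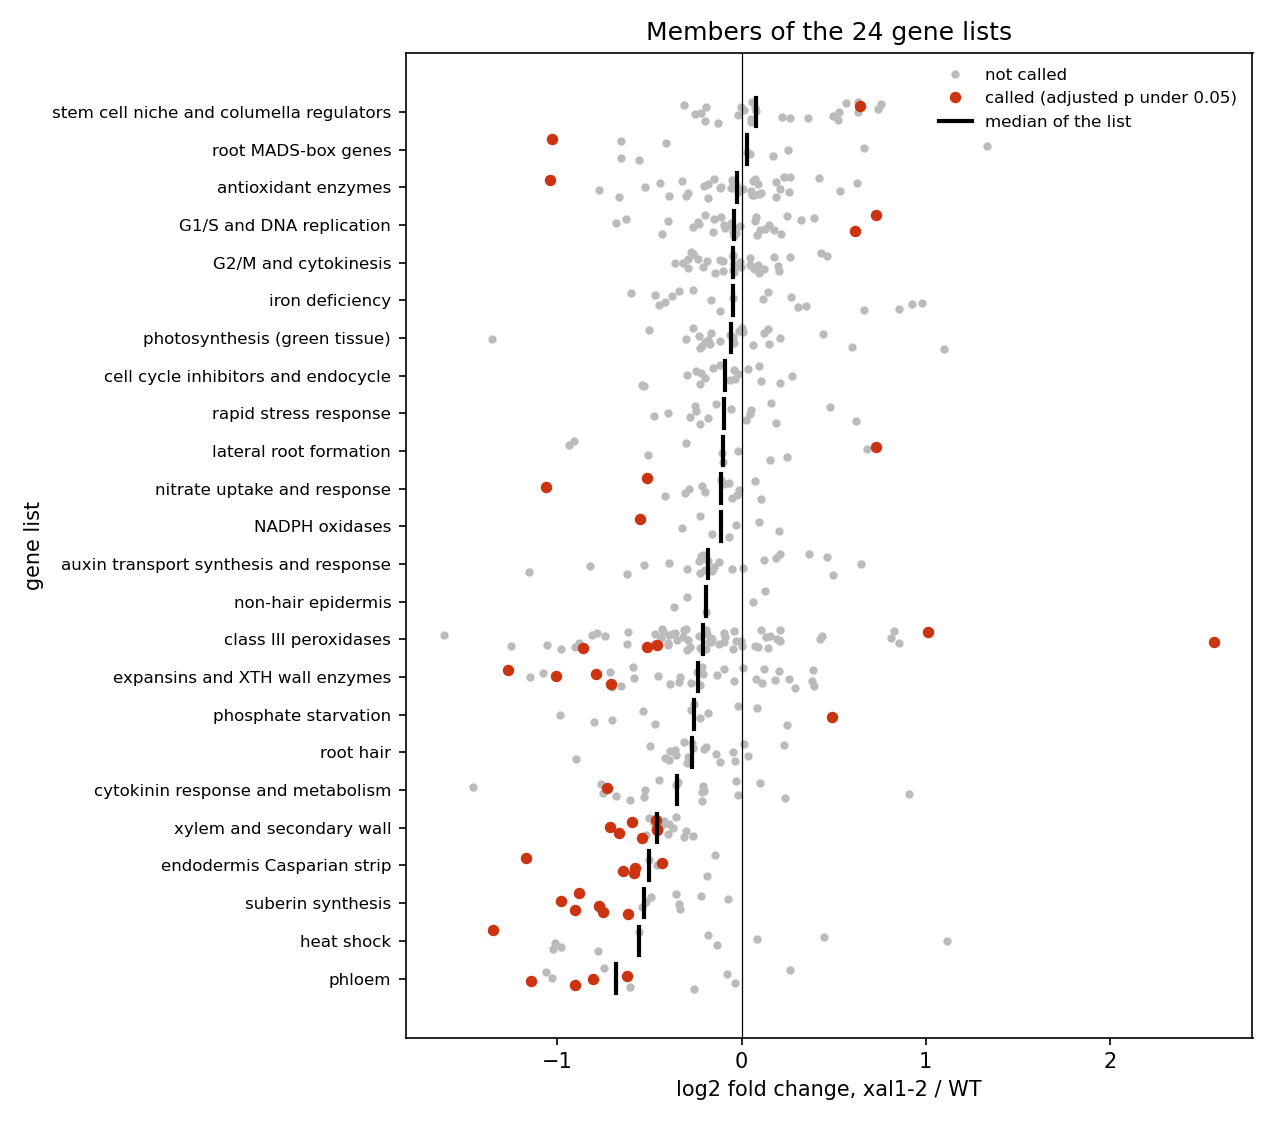
log2 fold change (x axis) of every tested member of the 24 gene lists (y axis), ordered by list median; red points were called by limma at adjusted p under 0.05, grey points were not, and the black line is the list median. The phloem, suberin, Casparian strip and xylem lists have their called members below 0, with medians from -0.68 to -0.46.

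Among wall-loosening enzymes, 4 of 34 expansin and XTH genes fell (7 fell and 2 rose adjusted over the list alone), namely EXLA2, EXPB3, XTH9 and XTH21. EXLA2 went from 89.2 ± 13.8 to 36.7 ± 8.47 (log2 fold change -1.27, SE 0.22, adjusted p = 0.0121). Of 15 nitrate uptake and response genes 2 fell, over all genes and over the list alone, the nitrate reductase gene NIA1 from 995 ± 175 to 474 ± 44.8 (-1.06, SE 0.13, adjusted p = 0.00176) and LBD37 (-0.51, SE 0.09). Of 20 cytokinin genes 1 fell, also over the list alone, the response regulator gene ARR5, from 592 ± 118 to 357 ± 81.4 (-0.73, SE 0.17, adjusted p = 0.041; edgeR adjusted p = 0.0511; also not called with a pseudocount of 0.1). Camera called these 3 lists lower (adjusted p = 0.00358, 0.00995 and 0.00358), with adjusted p = 0.349, 0.655 and 0.492 with an estimated correlation. The nitrate call was absent without WT replicate 2 or xal1-2 replicate 1 (adjusted p = 0.126 and 0.171), and without the latter no gene of the 3 lists was called by limma, with adjusted p of EXLA2, NIA1 and ARR5 up to 0.0964, 0.0584 and 0.219 over the libraries left out. Without WT replicates 1, 2 or 3 or xal1-2 replicates 2 or 3, 2, 0, 4, 3 and 3 expansin and XTH genes fell, 1, 1, 2, 2 and 1 nitrate genes, and 1, 0, 0, 0 and 3 cytokinin genes.

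The remaining lists were not called by camera. None of 25 auxin genes, 16 rapid stress response genes and 19 iron deficiency genes was called by limma, over all genes or over the list alone, nor by edgeR, DESeq2 or limma-voom, with 8, 0 and 1 at an unadjusted limma p under 0.05 (camera adjusted p = 0.261, 0.595 and 0.902). Leaving out xal1-2 replicate 3, 1 auxin gene rose and 1 fell, and leaving out WT replicate 3, 1 iron gene fell. The iron list had a median of -0.05 but a mean of 0.07 and a camera direction above 0, which turned below 0 with library totals. Its median was above 0 with library totals (0.011) and without WT replicates 1, 2 or 3 or xal1-2 replicate 1 (0.135, 0.069, 0.007 and 0.001). HSP18.2 was the single heat shock gene of 11 that fell, also over the list alone, from 89.1 ± 17.9 to 37.0 ± 17.9 (log2 fold change -1.35, SE 0.33, adjusted p = 0.0474; list adjusted p = 0.108). The phosphate transporter gene PHT1;4 rose from 1008 ± 158 to 1408 ± 62.6 (0.49, SE 0.12, adjusted p = 0.0456) in a list of 13 phosphate starvation genes whose median was -0.26 (adjusted p = 0.0527; 1 rose and 3 fell over the list alone). HSP18.2 lost its call without any library but xal1-2 replicate 3 and PHT1;4 without any 1 of the 6 (adjusted p up to 0.151 and 0.191), and HSP18.2 was not called with library totals, upper-quartile factors or pseudocounts of 0.1 or 5, nor PHT1;4 with a pseudocount of 0.1. In the phosphate list edgeR, DESeq2 and both filters on low values also called 1 gene lower, and the GC and length correction 2. Camera called the heat shock list lower without WT replicate 1, WT replicate 2 or xal1-2 replicate 3 (adjusted p = 0.0388, 0.0317 and 9.33e-05), the phosphate list lower without WT replicate 1, WT replicate 3 or xal1-2 replicate 3 (0.0278, 0.0211 and 0.0119), and both with library totals (0.0443).

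In the 3 lists built from the reference's product names, ribosomal proteins were higher as a list. Of 334 tested, 33 rose, 2 fell and 299 were not called (74 rose and 5 fell over the list alone), with a median log2 fold change of 0.23 (camera adjusted p = 6.46e-17; adjusted p = 0.349 with an estimated correlation). Among those that rose were the cytosolic ribosome genes RPSAb (0.75) and RPL16A (0.49), and NFD1 (0.58), which encodes a mitochondrial ribosomal protein. The list took product names with the words ribosomal protein, so it mixes compartments and holds eEF-1Bb1 (0.46), named for an elongation factor. Rises were not counted by compartment, so these examples show no share. Of 54 glutathione S-transferase genes 2 rose and 5 fell, and of 44 histone genes 1 fell. Adjusted over the list alone these counts were 2 and 5 for the transferases and 0 for the histones, 5 of which had an unadjusted limma p under 0.05, and edgeR called 1 histone gene. Camera called neither list (adjusted p = 0.427 and 0.413). Without WT replicates 1, 2 or 3 or xal1-2 replicates 1, 2 or 3 the ribosomal genes that rose numbered 9, 2, 24, 1, 3 and 12, the transferase genes called 2, 1, 4, 0, 1 and 4, and the histone genes that fell 0, 0, 0, 0, 0 and 1.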

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

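The edgeR test, TMM factors and the GC and length correction were chosen after the results were seen. XAL1 kept its direction and its call under every alternative run, with log2 fold changes from -1.55 to -1.34 without 1 library. The number of genes called (961) stayed within 1.5 times under the other scalings, pseudocounts, filters, count tests and corrections (733 to 1111). It was 194 at adjusted p under 0.01 and 2113 at unadjusted p under 0.05 with fold above 1.5, against 703 for the study threshold. These 2 thresholds differ by construction. Leaving out 1 library gave 81 to 871 called genes and 81 to 694 past the study threshold, the fewest without xal1-2 replicate 1. Of the 33 named genes called, 11 kept their call without any 1 library (XAL1, AT1G71691, AT5G52940, AT5G09570, NDB3, NDB4, MRD1, ATC, AT1G65020, AGL42 and CYP86A1), and 22 lost it in at least 1 such fit. None changed sign, which was fixed in advance because the genotypes did not overlap in these genes. The neighbour count fell from 1 to 0 in DESeq2 and with the filter at the lower quartile of mean values, because AT1G71691 then got no adjusted p.

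Of the lists called lower, those with adjusted p = 0.349 with an estimated correlation were suberin, Casparian strip, xylem, phloem and expansin (fry 0.0533, 0.0654, 0.044, 0.102 and 0.126), as was the ribosomal list called higher (fry 0.0654). It was 0.492 for peroxidases (fry 0.24) and cytokinin (fry 0.23), 0.726 for root hair (fry 0.604) and 0.655 for nitrate (fry 0.316). These settings allow members of a list to vary together. With library totals the stem cell niche list became called higher, and the heat shock and phosphate lists lower, each at adjusted p = 0.0443. The niche list was also called after the GC and length correction (0.0278) and with the replicate block (0.0354), and heat shock with the block (0.0078); the cause was not tested. Without 1 library the camera adjusted p ran from 0.000141 to 0.0655 for peroxidases, 5.61e-07 to 0.359 for root hair, 8.06e-05 to 0.171 for nitrate, 0.0123 to 0.234 for the niche, 9.33e-05 to 0.549 for heat shock, 0.0119 to 0.276 for phosphate and 0.000613 to 0.88 for photosynthesis.

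The replicate numbers gave no clear pairing of the libraries. Deviations of same-numbered libraries from their genotype means correlated at 0.01, 0.35 and -0.02 across 16417 genes. The highest of all pairs, 0.35, was a same-numbered one, and 3 libraries per genotype are too few to exclude a shared batch. With the replicate block 839 genes were called, among them 14 ribosomal protein genes higher, and 3 heat shock, 2 antioxidant and 1 root hair gene lower, but not PLT3 or PER20, and not every library correlated best with its own number. The planned median-of-ratios factors and the unfiltered set equal the main setting and were not run again. At this depth, spread and number of replicates together, genes changed 1.5-fold were recovered in 31.3% of simulated cases.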

Other observations

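The 4 lists of mitochondrial genes, the test of the other genetic difference, the tests of GC content, exon length and tissue share, the test of the size of the scaling shift, and the tests of position were chosen after the results were seen.

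Many genes of mitochondrial stress and protein quality control were higher in xal1-2. In 4 lists written from known functions after the calls had been seen, 26 members were called over all genes and all of them rose. The 26 include AT5G09570 (among the 7 reporters below), NDB3 and NDB4, already named above among the largest rises, so not all 26 are further genes. Adjusted over the list alone, 3 alternative respiratory, 7 reporter, 15 chaperone and 13 import genes rose, and 1 chaperone list member, FTSH10, fell (-0.28, SE 0.11). Among 11 mitochondrial stress reporters 7 rose, including UPOX (log2 fold change 3.97, SE 0.50, and 3.5 in edgeR), SLP2 (1.81, SE 0.15), the transcription factor gene NAC13 (1.24, SE 0.16) and UGT74E2 (1.63, SE 0.23). The WT libraries of UPOX were uneven (46.9 ± 48.1, against 549 ± 110 in xal1-2), and its edgeR adjusted p was 0.0499. Among the 4 reporters not called was BCS1, at 139 ± 118 in WT and 115 ± 24.9 in xal1-2. Among 20 chaperone, protease and prohibitin genes 12 rose, including PHB1 (0.98, SE 0.10), HSP60-2 (0.86, SE 0.13), mtHsc70-1 (0.78, SE 0.12), MGE1 (0.90, SE 0.15) and LON1 (0.72, SE 0.12). Of 22 import genes 4 rose, TOM7-2 most (1.48, SE 0.23), while 9 did with library totals and 8 in edgeR. Of 11 alternative respiratory genes tested 3 rose, NDB3, NDB4 and NDA1 (2.61, SE 0.33). AOX1A, the alternative oxidase gene commonly used as the marker of this response, was at 793 ± 113 in WT and 980 ± 86.9 in xal1-2 (n = 3, log2 fold change 0.31, SE 0.12) and was not called, nor was NAC017 (-0.15, SE 0.12), whose product controls much of it. Without xal1-2 replicate 1, 7 of these members were called: 3, 2, 2 and 0 of the alternative respiratory, reporter, chaperone and import genes. Without WT replicate 1 these numbers were 3, 6, 8 and 2, without WT replicate 2 they were 3, 5, 6 and 1, and without xal1-2 replicate 2 they were 3, 5, 7 and 2. As these lists were chosen for what they show, their tests (camera adjusted p = 0.0494 with an estimated correlation for each) are no independent evidence. The import list's median of 0.335 was not particular to it, against -0.004 over all genes. Product families with similar medians were 195 pentatricopeptide repeat genes (0.351), 263 tetratricopeptide repeat-like genes (0.306) and 31 mitochondrial transcription termination factor genes (0.316). None of these families passed the family test described below.

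Product families of at least 10 tested genes (324 families, Fisher's exact test one-sided, Benjamini-Hochberg over both directions) gave further falls in wall and barrier genes beside some already counted in the lists above, namely 2 of the laccases, 3 of the UPF0497 genes, 1 dirigent-like gene and 3 ABC-2 transporters that fell. Of 14 laccase genes, whose products oxidise lignin precursors, 8 fell (0.32 expected, adjusted p = 1.37e-07), LAC1 (-1.04) and LAC13 (-0.87) among them. Of 30 arabinogalactan protein genes 6 fell (0.7 expected, adjusted p = 0.00725), AGP30 most (-1.89), and of 37 UPF0497 genes, the family of the CASP proteins, 7 fell (0.86 expected, adjusted p = 0.00317). Of 64 genes of the lipid-transfer protein family 9 fell and 2 rose (1.48 and 1.07 expected, adjusted p = 0.00317 for the falls), and AT3G53980 dropped from 2180 ± 180 to 493 ± 66.5 (log2 fold change -2.15). Of 21 dirigent-like genes 5 fell (adjusted p = 0.0106), and of 18 genes named as transporters of ABC-2 type 4 fell (adjusted p = 0.0487). Of 18 DUF295 genes 5 rose and none fell (0.3 expected, adjusted p = 0.00292). AT5G52940, AT5G52930, AT5G54560 and AT4G25930 had no WT reads and were at least 89.2-, 20.7-, 22.9- and 10.7-fold higher against a floor of 3 reads over the WT group. Genes of the P-loop hydrolase family (10 of 165 rose and 3 fell, adjusted p = 0.0381 for the rises) and of a ribosomal protein family (4 of 22 rose, all 4 in the ribosomal list above, adjusted p = 0.0381) also passed. Some of these genes are tandem copies, so a family's calls are not independent. Some calls lay at the threshold, as for ABCG23 of the ABC-2 family (adjusted p = 0.0497), LAC7 (0.0497) and AT4G34670 of the ribosomal family (0.0499). The family counts use the calls of the main fit, and no other setting is given for them. Without xal1-2 replicate 1, where 81 genes were called in all, LAC11 and CASP5 lost their calls.

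The marneral cluster of chromosome 5 fell as a block of neighbours: MRN1 (log2 fold change -2.33), CYP705A12 (-1.36) and CYP71A16 (-0.70) were all called. On chromosome 1 the overlapping genes AT1G65010 and AT1G65020 moved in opposite directions, from 815 ± 55.8 to 2767 ± 457 (log2 fold change 1.75) and from 266 ± 16.0 to 30.8 ± 6.01 (-3.09). These genes were chosen after their values were seen.

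With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 961 called genes and 703 past the study threshold, and was the 1 split of 10 with as many in either count. The highest other split gave 9 in both.

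Scaling, GC content with exon length, and another genetic difference were set against the rise of the mitochondrial genes. After a per-library correction for GC content and exon length all 26 members stayed called, with their median log2 fold change going from 0.88 to 0.91, which argues against these as the whole cause. All 26 also stayed called under library totals, TMM and upper-quartile factors. These moved all genes upward by a median of at most 0.06, so upward calls could hardly be lost and this decides nothing. The members rose by 0.43 to 6.12, and 26 of them exceeded that shift by more than 2 SE, which their selection as called genes nearly ensured. Over all tested members, called or not, the medians were 0.311 (alternative respiratory), 1.235 (reporter), 0.521 (chaperone) and 0.335 (import). The small size of the shift beside these values argues against the choice among these scalings as the whole cause. The design has 1 mutant line, so an effect of XAL1 loss and one of another genetic difference carried by that line cannot be told apart. A hypothesis is that xal1-2 roots respond to a mitochondrial defect, which may follow from loss of XAL1 or from another difference of the line. Another allele or a complemented line would test which of these the rise follows from. Neither would test whether there is a mitochondrial defect, which was not measured here.

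For the fall of the suberin, Casparian strip, xylem and phloem genes, 22 members were called. Of these, 15 stayed called downward under all 3 other scalings and 17 after the GC and length correction, where their median went from -0.66 to -0.61, which argues against either as the whole cause. A smaller share of differentiated root in the mutant samples may also lower these lists, and predicts that proliferation genes rise. The mean log2 level of the 65 genes in the G1/S and G2/M lists differed by -0.03 (SE 0.08), from 6.88 in WT to 6.85 in xal1-2, which neither shows nor excludes a small rise. Slow cell division, which the series states for this mutant, could lower these genes and offset such a rise. The difference therefore decides nothing about the share of tissues. A smaller share of differentiated tissue and a lower expression within it thus cannot be told apart in whole roots.

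A linked variant around the mutated locus could add calls near XAL1. Within 1 Mb of XAL1, 18 of 529 tested genes were called (3.4%, against 3.96% elsewhere), an odds ratio of 0.85 (95% interval 0.5 to 1.37, Fisher's exact test two-sided p = 0.65). This interval argues against an excess there with an odds ratio above 1.37. A smaller excess, or a linked variant that changes a few genes, is not excluded. Over all 5 chromosomes, neighbouring tested genes were both called in 58 pairs, against a median of 38 pairs in 10000 random orders of the genes (permutation p = 0.0016). Called genes thus lay side by side more often than in random orders, which do not keep genes of similar level together. Of the 58 pairs 36 moved in the same direction, a number that was not tested. For larger groups only the maximum was tested: the highest number called among 10 neighbouring tested genes was 4, which random orders reached with permutation p = 0.98. It was reached in 12 windows, some overlapping, and that number was not tested. The maximum therefore cannot tell whether groups were more frequent than by chance. Whether shared regulation, a similar level of neighbouring genes, reads shared between copies or overlapping genes made the pairs was not tested.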
